A study of Mus musculus with 9 samples.

How the data were processed

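Mouse embryonic stem cells of the male C57BL/6J line Bruce 4 were grown, per the labels' protocols, on laminin-511 in 3 media with 3 libraries each. The control medium (Std) held 15% serum and 1000 U/mL leukaemia inhibitory factor (LIF). The 2i medium added 1 µM of the MEK inhibitor PD0325901 and 3 µM of the GSK3 inhibitor CHIR99021. The PD-MK medium added 1 µM PD0325901 and 4 µM of the Akt inhibitor MK-2206. CEL-Seq2, a 3'-end method with unique molecular identifiers (UMIs), was run on 30 to 60 ng of RNA per library. The labels call the replicates biological and name no batch. The label text also carries an index from 1 to 9 for each library, and PD-MK holds indices 1 to 3.

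The values used were the UMI counts per gene deposited by the authors, who mapped reads with HISAT2 2.1.0 to GRCm38 (mm10) and counted them with HTSeq, per the submitters' processing notes. The annotation release, the UMI length and the strand setting of the counting are not given in the sources used here. The table held 50689 genes and 92 ERCC spike-in transcripts, of which 76 were detected. ERCC transcripts totalled only 180 to 303 UMIs per library, and spike-in scaling rests on these totals. Positions came from GENCODE M21 (GRCm38), which held 50462 of the gene identifiers and gave the same symbol for 47683. Symbols shared with another entry occurred in 102 extra entries, and 7 tested genes shared a symbol.

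Totals ran from 669305 to 1947767 UMIs per library. A count of 0 in a group allowed up to 3 UMIs over its libraries, which was 1.08 CPM in PD-MK and 0.644 CPM in Std. Such floors, and the 95% intervals of ratios given for genes with 1 to 3 UMIs in a group, cover counting error only. Genes with 1 to 3 UMIs were given a ratio with its interval, and genes with 0 were given a smallest fold difference from the floor. The highest count in any library was 4090, just under the 4096 tags that 6 bases allow. A UMI length of 6 bases was inferred from those values, and a correction for tags drawn more than once was computed on that assumption. It put the UMIs lost to such collisions at 8.64% to 18.2% per library, so that under this assumption abundant genes are counted too low, and more so in deeper libraries.

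Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 9740. Counts were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, robust, two-sided) in R 4.3.3, with 6 residual degrees of freedom and a biological coefficient of variation of 18.2%. P values were Benjamini-Hochberg adjusted over all tested genes, and genes under 0.05 were called changed. Errors of log2 fold changes are standard errors (SE) from the quasi-likelihood statistic, with 3 libraries per group. A value given after a gene name without a unit is its log2 fold change ± SE. Expression is given as CPM on TMM-scaled totals, as mean ± SD over 3 libraries, and the prior count for log2 values was 0.125. Library measures were compared with two-sided exact permutation tests, in which 3 against 3 libraries cannot give a p under 0.1. The 3 comparisons were PD-MK against Std, 2i against Std, and PD-MK against 2i. Genes set apart by a medium were those called in the same direction against both of the others.

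Gene lists were fixed before the data were examined. They covered naive pluripotency, core pluripotency, formative and primed epiblast, ERK targets, Wnt/beta-catenin targets, FoxO targets, LIF/STAT3 targets, DNA methylation machinery, germline genes, 2-cell stage genes, cholesterol synthesis, glycolysis, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, ribosomal proteins, ATF4 targets, p53 targets, cell cycle, lysosome and autophagy, and markers of primitive endoderm, trophoblast, mesendoderm, neuroectoderm and fibroblasts. Each list was tested against all other genes with limma 3.58.1 camera (preset correlation 0.01), adjusted over the 66 list tests, where at least 3 members were tested. The camera test was repeated with an estimated correlation, and fry was run as a test of the lists on their own. Lists are described as called or not by camera unless fry is named. The estimated version of camera also judges its statistic on the residual degrees of freedom of the fit. Its p values can thus rise without correlated list members. The trophoblast list in PD-MK against Std had an estimated correlation of -0.057, below the preset. Its unadjusted camera p still went from 1.29e-06 to 0.00248. Counts are given over all genes and also adjusted over the list alone.

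The genes named were chosen by a rule fixed before the data were examined. It took the 8 largest rises and the 8 largest falls of each comparison among called genes with a mean of at least 20 CPM and non-overlapping groups, leaving out predicted genes, clone-named genes and pseudogenes. It also took up to 3 called members in each direction per list, by adjusted p, and always a fixed set that included Nanog, Pou5f1, Sox2, Esrrb, Klf4, Zfp42, Dusp6, Spry4, Axin2, Dnmt3a, Dnmt3b, Dnmt3l, Irs2, Map2k1, Map2k2, Gsk3a, Gsk3b, Akt1 and Akt2. Of the 188 genes this named, 6 shared at least 20% of the 50-nt words in their last 500 nt with other genes. On the same strand 39 overlapped another gene, and on the opposite strand 76 did.

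The alternatives fixed before the data were examined included RLE and spike-in scaling, library totals, DESeq2 1.42.0, no expression filter, a strict filter of 5 CPM in 3 libraries, fits on only the 6 libraries of a comparison, a replicate block, and leaving out each library in turn. Added after the data were seen were a term for indices 1 to 5 against 6 to 9, the libraries of indices 1 to 5 alone, a term for Std 2 and 2i 3, their removal, thinning to the shallowest library, removal of each library's GC trend, and the collision correction. The index term can be estimated only from Std and 2i, since all PD-MK libraries lie on the low side. For the shared effect of the inhibitor media, 20 simulations of unchanged groups against a common control gave the correlation that sharing Std alone produces.

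The pipeline was tested on simulated data with 200 changed genes. It called 4-fold changes in 87.6% to 93.1% of cases, 2-fold changes in 38.5% to 43.2% and 1.5-fold changes in 4.66% to 6.73%, and 6.36% to 8.55% of the called genes were unchanged ones. Figures were drawn with matplotlib 3.10.9. ERCC transcripts were left out of the tests, and reads were not analysed here.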

Results

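RNA was measured in 9 CEL-Seq2 libraries of mouse embryonic stem cells, with 3 libraries in serum and LIF (Std), 3 with MEK and GSK3 inhibitors added (2i), and 3 with MEK and Akt inhibitors added (PD-MK). The libraries held 1467906, 1161469 and 1947767 UMIs in Std, 1451789, 1905765 and 1372463 in 2i, and 946415, 1346937 and 669305 in PD-MK. Mean totals were 1.53 ± 0.398 M UMIs in Std, 1.58 ± 0.291 M in 2i and 0.988 ± 0.342 M in PD-MK (SD, n = 3; exact permutation test against Std, two-sided, p = 1 for 2i and p = 0.2 for PD-MK, smallest possible 0.1). Between 13610 and 16202 genes were detected per library. Totals and detected genes also split by index. Indices 1 to 5 (PD-MK, 2i 3 and Std 2) held 669305 to 1372463 UMIs and 13610 to 15576 genes. Indices 6 to 9 held 1451789 to 1947767 UMIs and 15691 to 16202 genes. Mitochondrially encoded transcripts made up 1.06% ± 0.0596 of UMIs in Std, 1.14% ± 0.0809 in 2i and 1.46% ± 0.243 in PD-MK (SD, n = 3; exact permutation test of PD-MK against Std, p = 0.1). Corrected for UMI collisions, if the UMI had 6 bases, these shares were 1.501%, 1.71% and 1.91%. The first principal component held 46.3% of the variance and the next 22.1%.

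Some genes followed the library index rather than the medium. Tbcd stood at 936.2 CPM in Std 2 and 843 CPM in 2i 3, against 317.9 and 329.7 CPM in Std 1 and Std 3, 340.7 and 368.3 CPM in 2i 1 and 2i 2, and 1051 to 1244 CPM in PD-MK. Rassf7 shifted upwards and Mif-ps3 downwards in the same libraries (these 3 genes were chosen after their values were seen). PD-MK holds indices 1 to 3, 2i 3 holds 4 and Std 2 holds 5. A term for Std 2 and 2i 3 called 1480 genes (782 up, 698 down), of which 243 at least doubled or halved. Among ribosomal protein genes 11 were up and 21 down of 74 in these libraries (camera adjusted p = 0.0475), and among oxidative phosphorylation genes 3 were up and 10 down of 38 (camera adjusted p = 0.0475). These p values were adjusted over the lists of this term alone, and no estimated correlation was computed. The term was chosen after these libraries were seen to deviate together, so the p values describe that grouping and do not test it independently. Because all PD-MK libraries lie on the low side, PD-MK and index separate only through Std 2 and 2i 3. What the index stands for, such as a processing order or a barcode number, is not given in the sources used here. Counts of changed genes are therefore given also with an index term and within indices 1 to 5 alone, and called lists also with the index term. Of the calls for named genes 33 were lost with the index term and 123 within indices 1 to 5, where fewer libraries entered, and such losses are given for the genes reported here as changed.

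**Figure D1:**
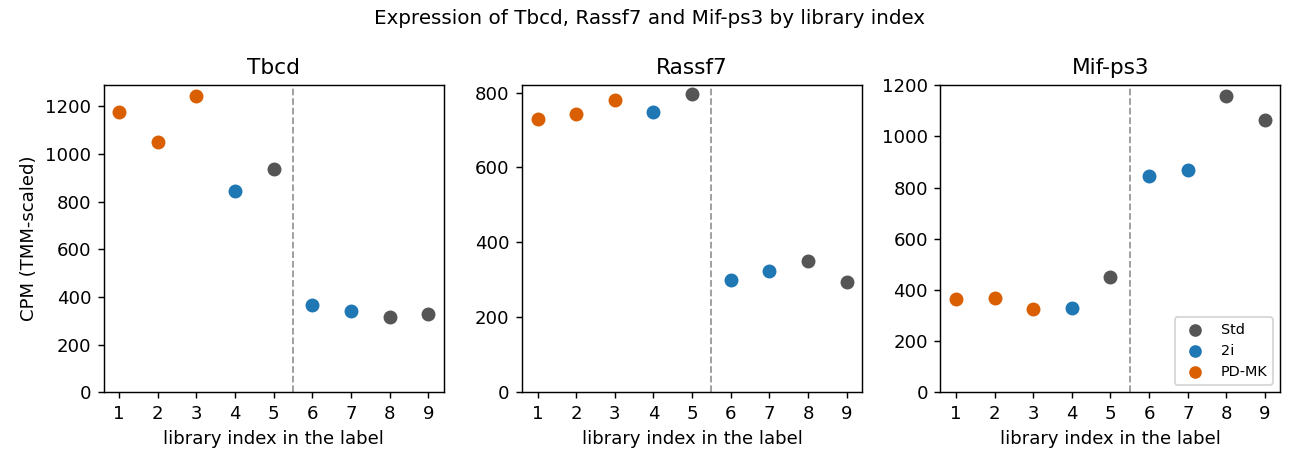
CPM (TMM-scaled, vertical axis) of Tbcd, Rassf7 and Mif-ps3 in each of the 9 libraries against the index in the labels (horizontal axis), coloured by medium, with a dashed line between indices 5 and 6. Std 2 (index 5, Tbcd 936.2 CPM) and 2i 3 (index 4, 843 CPM) lie nearer to the PD-MK libraries than to the other libraries of their own medium.

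The comparison of PD-MK with Std asks which genes differ when MEK and Akt are inhibited in serum and LIF. The homeobox gene Vax2 (ENSMUSG00000034777, GRCm38 chr6:83711264-83738313) rose from 7.85 ± 4.73 to 265.7 ± 13.9 CPM (log2 fold change 5.18 ± 0.348, adjusted p = 3.1e-07), and reads of Vax2os, which overlaps it on the opposite strand and rose by 4.47 ± 0.261, could not be told apart without the strand setting. Hoxc11 (ENSMUSG00000001656, chr15:102954427-102957708) had 1 UMI in Std and 76 in PD-MK, a ratio of 126 (95% interval 22.2 to 5100). Gsc, an organiser homeobox gene, rose from 1.58 ± 0.518 to 63.7 ± 10.3 CPM (log2 fold change 5.33 ± 0.463, adjusted p = 1.69e-06). Among the falls, the keratin gene Krt18 (ENSMUSG00000023043, chr15:102028180-102032027) went from 399.6 ± 124 to 7.08 ± 1.05 CPM (log2 fold change -5.85 ± 0.316, adjusted p = 9.81e-08), and Krt7 had a log2 fold change of -5.00 ± 0.419. Anxa3 (ENSMUSG00000029484, chr5:96793339-96845966) was at 65.5 ± 16.6 CPM in Std and had no UMI in PD-MK, at least 60.7-fold lower (adjusted p = 1.71e-05). Slc1a3 was lower by a ratio of 0.0048 (95% interval 0.000768 to 0.0231). Igf2 (ENSMUSG00000048583, chr7:142650766-142666816) had a log2 fold change of -5.31 ± 0.385, although 100% of its searched 3' sequence is shared with the overlapping Gm49394.

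Of 9740 genes, 2651 changed (1319 rose, 1332 fell), 801 at least doubled and 821 at least halved. With the index term 2241 changed (1144 rose, 1097 fell), 1826 of them also called without it and 0 of those in the other direction (edgeR; 3834 genes had an unadjusted p under 0.05 in the pooled fit). Within indices 1 to 5, where 3 PD-MK libraries faced Std 2 alone, 1227 changed (648 rose, 579 fell), on the assumption that Std 2 varies as the other libraries do. Of the genes reported here as changed, Esrrb, Zfp42, Sox2, Etv5, Irs2, Gsk3b, Akt1, Map2 and mt-Co1 were not called there. Without Std 3 the pooled count was 1739. Scaling by library totals gave an all-gene median log2 fold change of -0.13, against -0.01 with TMM, and left 38.7% of the called genes as rises, against 49.8% with TMM, and turned the medians of the core pluripotency (-0.07), FoxO (-0.11) and cell cycle (-0.04) lists negative. Spike-in scaling gave a median of -0.56 and left 14%, and turned the median log2 fold changes of the core pluripotency (0.06 to -0.52), LIF/STAT3 (0.27 to -0.28), DNA methylation (0.33 to -0.20), mitochondrially encoded (0.42 to -0.11), lysosome (0.44 to -0.12), primitive endoderm (0.17 to -0.34), cell cycle (0.08 to -0.46) and FoxO lists negative.

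Naive pluripotency genes, which mark the state of the preimplantation epiblast, mostly rose in PD-MK. Tbx3 went from 127.9 ± 10.2 to 619.5 ± 23.1 CPM (log2 fold change 2.27 ± 0.165, adjusted p = 3.71e-07), Tfcp2l1 had a log2 fold change of 1.41 ± 0.158 and Nanog went from 99.25 ± 18.9 to 283.3 ± 43 CPM (1.502 ± 0.189, adjusted p = 4.38e-05; 1.79 with the index term). Klf4 rose by 0.81 ± 0.169 (adjusted p = 0.00255) and Esrrb by 0.51 ± 0.131 (adjusted p = 0.00937; -0.03 with spike-in scaling). Zfp42 was called (2.06 ± 0.512, adjusted p = 0.00823) but not without Std 3 (adjusted p = 0.0515), and Gbx2 fell (-1.95 ± 0.28). Of the 20 list members 13 rose and 2 fell (15 and 2 adjusted over the list alone). The list lay above other genes (median 0.93, camera adjusted p = 1.34e-07, and adjusted p = 0.0541 with an estimated correlation). With the index term 14 rose and 1 fell (camera adjusted p = 2.59e-12, and 0.028 with an estimated correlation). Of the core pluripotency list 6 rose and 5 fell of 18 (6 and 6 adjusted over the list alone, adjusted p = 0.737), with a median of 0.06 but a mean of -0.09. Epcam (-2.04 ± 0.24), Utf1 (-1.17 ± 0.188) and Lin28a (-1.15 ± 0.217) fell and Gdf3 rose (1.25 ± 0.174). Pou5f1 averaged 14.6 CPM in PD-MK and 7.44 CPM in Std and was not called (log2 fold change 1.00 ± 0.74, adjusted p = 0.346). Its count was low beside that of Nanog. It shares 2.66% of its searched 3' sequence with Gm5712, and Gm19553 overlaps it on the opposite strand. Reads were not analysed here, so whether the count holds most of its transcripts is not known, and its level should not be read from it. Sox2 was called at 0.51 (adjusted p = 0.0437) but not with the index term (adjusted p = 0.192), nor without Std 1 (0.0991), Std 3 (0.192), 2i 1 (0.0573), PD-MK 1 (0.108) or PD-MK 3 (0.184).

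ERK feedback genes, which report MEK activity, fell in PD-MK. Etv4 went from 410.2 ± 52.5 to 17.4 ± 5.02 CPM (log2 fold change -4.50 ± 0.32, adjusted p = 3.71e-07), Dusp6 from 23.3 to 2.11 CPM (-3.62 ± 0.475, adjusted p = 6.09e-05) and Spred1 had a log2 fold change of -2.27 ± 0.249. Etv5 alone of the list was called higher (0.55 ± 0.145, adjusted p = 0.0118), but not without Std 1 (0.0594) or PD-MK 2 (0.0617). Of 16 members 9 fell and 1 rose (9 and 1 adjusted over the list alone, adjusted p = 5.48e-06, and adjusted p = 0.0541 with an estimated correlation; adjusted p = 4.19e-06 with the index term). Of the FoxO targets, genes that Akt activity keeps low, 6 rose and 4 fell of 21 (7 and 4 adjusted over the list alone, adjusted p = 0.824). With fry, which does not set a list against other genes, that list was called higher (adjusted p = 0.0206). Cited2 rose (2.27 ± 0.359) and Foxo1 fell (-1.14 ± 0.174). Irs2 was called at 0.81 (adjusted p = 0.0332) but not with the index term (adjusted p = 0.316), nor without Std 1 (0.117), Std 3 (0.0975), PD-MK 1 (0.071), PD-MK 2 (0.0801) or PD-MK 3 (0.0776). Of the genes for the kinases that the inhibitors target, Gsk3b rose (1.11 ± 0.223, adjusted p = 0.00209) and Akt1 was called lower (-1.85 ± 0.443, adjusted p = 0.00656; adjusted p = 0.0503 with the index term). Gsk3b was also called higher in 2i than in Std (0.68, adjusted p = 0.0401), but not without Std 1 (0.171), Std 3 (0.169), 2i 1 (0.0674), 2i 2 (0.0767), 2i 3 (0.0866), PD-MK 1 (0.0505) or PD-MK 3 (0.0572), nor within indices 1 to 5. Akt2, Map2k1, Map2k2 and Gsk3a were not called in PD-MK against Std (adjusted p = 0.383, 0.329, 0.45 and 0.524).

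Cholesterol synthesis genes rose in PD-MK. Hmgcs1 went from 180.8 ± 24.8 to 435.5 ± 84 CPM (log2 fold change 1.27 ± 0.194, adjusted p = 2.32e-04), Msmo1 rose by 1.04 ± 0.143 and Nsdhl by 0.99 ± 0.162. Of 22 members 13 rose and 0 fell (17 and 0 adjusted over the list alone, median 0.84, adjusted p = 3.85e-06, and adjusted p = 0.0561 with an estimated correlation; 15 rose with the index term, adjusted p = 6.43e-07). Lysosome and autophagy genes included Npc2 (1.24 ± 0.145), Grn (1.04 ± 0.142) and Asah1 (1.30 ± 0.196) among 11 that rose, with 1 that fell, of 28 (13 and 1 adjusted over the list alone, adjusted p = 0.00433, and adjusted p = 0.0561 with an estimated correlation; adjusted p = 0.00177 with the index term). Among glycolysis genes Pdk1 (-2.44 ± 0.279), Slc2a1 (-1.10 ± 0.149) and Pfkl (-1.16 ± 0.201) fell, 6 fell and 0 rose of 19 (6 and 0 adjusted over the list alone), and the list was not called (adjusted p = 0.0615). It was called with the index term (adjusted p = 8.71e-04), with library totals (0.0363), and without Std 1 (0.036), Std 3 (0.0303) or PD-MK 3 (0.0202). None of these calls stayed with an estimated correlation (lowest adjusted p = 0.253, with the index term).

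Lineage genes moved in different directions. The trophoblast list fell (adjusted p = 9.43e-06, and adjusted p = 0.0541 with an estimated correlation; adjusted p = 9.15e-07 with the index term), with 3 of 7 members lower and 0 higher (4 and 0 adjusted over the list alone), among them Hand1 at a ratio of 0.0284 (95% interval 0.00657 to 0.0959). The neuroectoderm list rose (adjusted p = 0.0178, and adjusted p = 0.148 with an estimated correlation; adjusted p = 0.0234 with the index term). Sox1 (2.70 ± 0.359), Tubb3 (1.94 ± 0.423) and Ncam1 (1.56 ± 0.212) rose and 1 of 5 was called lower (4 and 1 adjusted over the list alone). The lower call, Map2 (-1.52 ± 0.439, adjusted p = 0.0189), was lost with the index term (0.162) and without Std 1 (0.11), PD-MK 1 (0.0518), PD-MK 2 (0.0555) or PD-MK 3 (0.0608). Germline genes fell as a list (6 fell and 1 rose of 13, the same adjusted over the list alone, adjusted p = 0.00431, and adjusted p = 0.0561 with an estimated correlation; adjusted p = 0.00107 with the index term). Rhox5 had a log2 fold change of -2.81 ± 0.269, Piwil2 at -3.08 ± 0.325 and Dmrt1 at -2.30 ± 0.301. Of the formative and primed epiblast genes 7 fell and 4 rose of 14 (the same adjusted over the list alone). The de novo methyltransferase genes Dnmt3a (-1.61 ± 0.173, adjusted p = 1.1e-05) and Dnmt3b (-1.76 ± 0.192, adjusted p = 1.22e-05) fell, and Zic2 rose (2.05 ± 0.232). That list was not called (adjusted p = 0.105), but was with the index term (adjusted p = 0.0497) and without Std 1 (0.0307), Std 3 (0.0374) or 2i 3 (0.0379). None of these calls stayed with an estimated correlation (adjusted p = 0.493 with the index term, and lowest 0.156, without Std 1).

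The comparison of 2i with Std asks which genes differ when MEK and GSK3 are inhibited. Plagl1 (ENSMUSG00000019817, GRCm38 chr10:13060504-13131694) rose from 8.29 ± 4.33 to 207.9 ± 6.77 CPM (log2 fold change 4.63 ± 0.305, adjusted p = 1.33e-07), and the homeobox gene Meis2 from 1.12 ± 0.765 to 42.5 ± 3.19 CPM (5.19 ± 0.394). Hoxc11 rose from 1 UMI in Std by a ratio of 202 (95% interval 37.3 to 8320), and Npr3 by 5.10 ± 0.33. The splicing regulator Esrp1 (ENSMUSG00000040728, chr4:11331933-11386783) fell from 62.1 ± 6.93 to 0.781 ± 0.697 CPM (-6.08 ± 0.414, adjusted p = 1.57e-07), and Krt18 fell to 25.5 ± 4 CPM (-3.97 ± 0.248, adjusted p = 1.3e-07). Nrp2 (-4.35 ± 0.274) and Nnat (-5.21 ± 0.369) also fell. In all, 1965 genes changed (1079 rose, 886 fell), 703 at least doubled and 576 at least halved. With the index term 2823 changed (1477 rose, 1346 fell), among them 1957 called without it. Without Std 2 and 2i 3, which left 2 libraries each of 2i and Std, 2251 changed (1230 rose, 1021 fell). That fit still held the 3 PD-MK libraries, so its spread is not from indices 6 to 9 alone. Within indices 1 to 5 the fit sets 1 library against 1. Its calls rest on the spread of the 3 PD-MK libraries alone, and Dusp6, Ascl2, Gsk3b and Zfp42 were not called in it. Both 2i (indices 4, 6 and 7) and Std (5, 8 and 9) have libraries on each side of the index term, so the term here rests on both media. On each side the 2i indices lie below the Std indices, so the term does not remove a trend along the index.

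In 2i the naive list also rose. Tbx3 went to 514.1 ± 90 CPM (log2 fold change 2.00 ± 0.163, adjusted p = 8.28e-07), Nanog to 248 ± 32.9 CPM (1.31 ± 0.186, adjusted p = 1.12e-04), Jam2 rose by 2.08 ± 0.141 and Tfcp2l1 by 1.61 ± 0.158, while Gbx2 (-2.37 ± 0.266) and Dppa3 (-1.72 ± 0.371) fell. Of 20 members 12 rose and 2 fell (13 and 2 adjusted over the list alone, adjusted p = 3.53e-06, and adjusted p = 0.0541 with an estimated correlation; 7.03e-09 with the index term). Esrrb was not called (0.15 ± 0.13, adjusted p = 0.499), nor was Sox2 (-0.09, adjusted p = 0.778). Zfp42 was called at 1.58 (adjusted p = 0.0343) but not without Std 3 (0.176), 2i 1 (0.0953) or 2i 2 (0.0939). Pou5f1, with the limit on its low count given above, was not called (1.56 ± 0.649, adjusted p = 0.119) but was without 2i 1 (0.0473) or 2i 3 (0.0239). The core list fell (5 fell and 1 rose of 18, the same adjusted over the list alone, adjusted p = 0.00713, and adjusted p = 0.0646 with an estimated correlation; 7.05e-04 with the index term). Lin28a went from 550.3 to 61.4 CPM (-3.16 ± 0.236, adjusted p = 3.72e-07) and Utf1 had a log2 fold change of -2.19 ± 0.193. The formative list fell (9 fell and 2 rose of 14, the same adjusted over the list alone, adjusted p = 2.92e-08, and adjusted p = 0.0541 with an estimated correlation; 1.25e-08 with the index term). Dnmt3a went from 140.9 to 24.7 CPM (-2.51 ± 0.175, adjusted p = 1.88e-07) and Lefty1 had a log2 fold change of -3.16 ± 0.272.

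ERK targets fell in 2i as well. Etv4 went to 35.1 ± 18.3 CPM (log2 fold change -3.57 ± 0.28, adjusted p = 7.05e-07) and Dusp6 had a log2 fold change of -4.14 ± 0.437 (adjusted p = 7.37e-06; not called within indices 1 to 5 alone). Of 16 members 11 fell and 0 rose (12 and 0 adjusted over the list alone, adjusted p = 7.43e-09, and 7.03e-09 with the index term), and of all 66 list tests of the pooled fit only this call stayed with an estimated correlation (adjusted p = 0.0399). With the index term, camera with an estimated correlation kept the naive (adjusted p = 0.028 in PD-MK, 0.0331 in 2i) and ERK lists (0.0425 in each) against Std. It also kept the formative (0.048), lysosome (0.0461) and trophoblast (0.048) lists in 2i against Std, and p53 targets in PD-MK against 2i (0.0425). No other list call stayed in that fit, whose term was added after the data were seen. The lysosome list rose (15 rose and 1 fell of 28, the same adjusted over the list alone, adjusted p = 4.2e-04, and adjusted p = 0.0541 with an estimated correlation; 5.16e-05 with the index term). Npc2 had a log2 fold change of 1.48 ± 0.144 and Atp6v1a at 1.34 ± 0.188. The trophoblast list fell (4 fell and 2 rose of 7, the same adjusted over the list alone, adjusted p = 0.00117, and adjusted p = 0.0541 with an estimated correlation; 2.32e-05 with the index term), with Hand1 at a ratio of 0.0106 (95% interval 0.00148 to 0.0453) and Krt7 at -2.82 ± 0.297, but Tfap2a higher at a ratio of 21.1 (95% interval 6.19 to 200). Of the Wnt/beta-catenin targets, which GSK3 inhibition derepresses, 5 were tested and only Ascl2 was called (-0.66, adjusted p = 0.0132; adjusted p = 0.0763 without 2i 1; list adjusted p = 0.351, 1 fell adjusted over the list alone). Axin2, below the expression filter, had 0 UMIs in each Std library, 4, 4 and 5 in 2i, and 1, 2 and 1 in PD-MK. Spry4, also below it, had 9, 13 and 11 in Std, 0 in each 2i library, and 1, 0 and 0 in PD-MK.

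Among cell-cycle regulators, the inhibitor gene Cdkn1a rose in 2i from 142.4 ± 42.1 to 490.5 ± 120 CPM (log2 fold change 1.78 ± 0.227, adjusted p = 4.4e-05) and Ccnd2 fell (-4.28 ± 0.49). The cell cycle list was not called (3 rose and 3 fell of 32, the same adjusted over the list alone, adjusted p = 0.949). Of p53 targets 5 rose and 2 fell of 18 (9 and 2 adjusted over the list alone, adjusted p = 0.105). That list was called with the index term (adjusted p = 0.0223), but not with an estimated correlation (adjusted p = 0.109). Germline genes included Dazl, from 23.8 to 133.8 CPM (2.44 ± 0.253, adjusted p = 6.13e-06), but 6 fell and 2 rose of 13 (7 and 5 adjusted over the list alone, adjusted p = 0.411). Cholesterol synthesis was not called in 2i (2 rose and 0 fell of 22; 0 adjusted over the list alone, adjusted p = 0.225), nor was glycolysis (2 rose and 2 fell of 19, the same adjusted over the list alone, adjusted p = 0.953), where Hk1 rose (1.28 ± 0.169) and Pdk1 fell (-1.64 ± 0.252). ATF4 targets were not called (2 rose and 7 fell of 24; 2 and 8 adjusted over the list alone, adjusted p = 0.0833), with Asns higher (1.40 ± 0.183) and Chac1 lower (-1.78 ± 0.239). That list was called without Std 1 (adjusted p = 0.0492) or 2i 2 (0.0498), but in neither case with an estimated correlation (adjusted p = 0.302 for each).

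The fold changes of the inhibitor media against Std went together across genes. Krt18, Etv4 and Igf2 fell and Tbx3, Nanog and Hoxc11 rose in both. Pearson's correlation across 9740 genes was 0.751 and Spearman's 0.634, against 0.469 ± 0.0115 and 0.448 in 20 simulations (mean ± SD) of unchanged media set against a common Std. The simulated counts were drawn from the Std means and filtered again, which kept a mean of 9052 genes. The observed and simulated values thus cover different sets of genes. The covariance was 0.706 against a simulated 0.0461, a difference of 0.66. In both comparisons 672 genes rose (146.1 expected from the product of the counts) and 562 fell (121.2 expected), and 14 changed in opposite directions. In the simulations edgeR called 0 genes in both comparisons, so they give no overlap to set these counts against. With the index term the correlation was 0.764, and within indices 1 to 5 it was 0.779. The simulated values belong to the pooled fit and were not computed for these, and sharing the lone library Std 2 raises the correlation that unchanged media would give. Part of the excess over the expected overlap may come from the shared controls, since 3 Std libraries cannot be split into sets of at least 2. Both media also held the same 1 µM of PD0325901. No group had a single inhibitor, so neither the agreement nor the differences of the media can be assigned to 1 of them. Genes are not independent replicates.

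**Figure D2:**
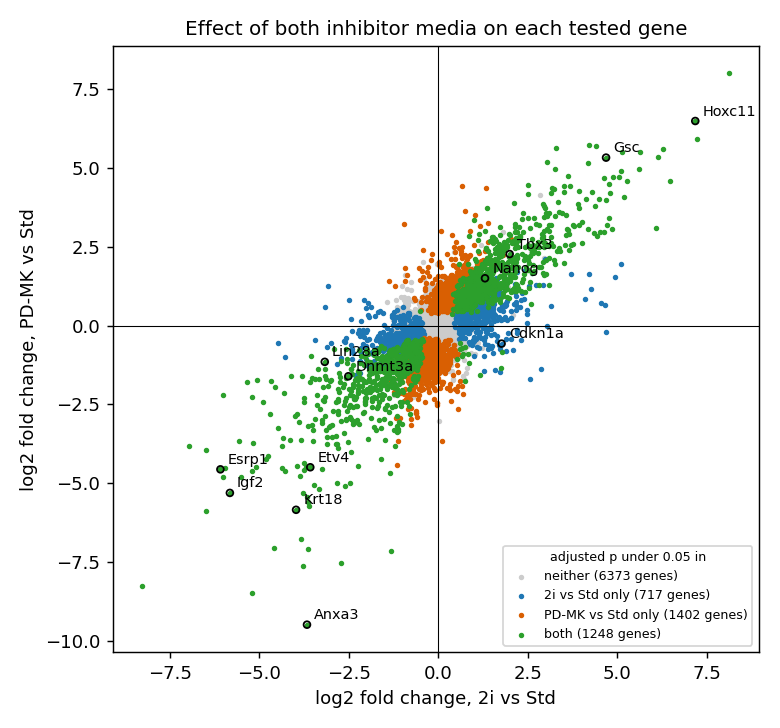
Log2 fold changes of 9740 genes in 2i against Std (horizontal axis) and PD-MK against Std (vertical axis), with points coloured by the comparison in which edgeR called the gene. In both comparisons 672 genes rose and 562 fell, while 14 went in opposite directions.

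The comparison of PD-MK with 2i asks what differs between Akt and GSK3 inhibition beside the same MEK inhibitor. Eras (ENSMUSG00000031160, GRCm38 chrX:7924276-7928607), which codes for a Ras protein of embryonic stem cells, was higher in PD-MK at 89.2 ± 6.65 against 13.8 ± 4.85 CPM (log2 fold change 2.64 ± 0.292, adjusted p = 1.06e-04). The homeobox gene Otx2 (chr14:48657677-48673819) was higher at 233.2 ± 26.6 against 61.1 ± 14.5 CPM (1.94 ± 0.195, adjusted p = 6.19e-05), as were Stat4 (2.57 ± 0.335) and Nnat (2.94 ± 0.46). Cdkn1a (ENSMUSG00000023067, chr17:29090976-29100727) was lower at 96.2 ± 6.35 against 490.5 ± 120 CPM (-2.35 ± 0.24, adjusted p = 6.19e-05). Anxa8 (ENSMUSG00000021950, chr14:34085981-34100571) was lower at 7.36 ± 2.54 against 69.7 ± 14.6 CPM (-3.19 ± 0.329, adjusted p = 6.19e-05), as was Ckmt1 (-3.10 ± 0.295). In all, 1215 genes differed (549 higher and 666 lower in PD-MK), with 266 at least doubled and 415 at least halved. With the index term 904 differed (408 higher, 496 lower), 691 of them among the pooled calls, and within indices 1 to 5, against 2i 3 alone, 279 did (117 higher, 162 lower). Not called there were Utf1, Cdh1, Dnmt3a, Irs2, Cited2, Ccng1, Ccnd2, Eomes and Vim. The pooled count was 551 without 2i 1, 554 without 2i 2, 1975 without 2i 3, 603 without PD-MK 1, 732 without PD-MK 2 and 660 without PD-MK 3. Scaling by library totals gave an all-gene median of -0.14, against -0.01 with TMM, and left 28.4% of the calls higher in PD-MK, against 45.2% with TMM, and turned the ATF4 median from 0.08 to -0.05. Spike-in scaling gave a median of -0.57, left 4.84%, and turned the list medians of naive (0.25 to -0.38) and core pluripotency (0.44 to -0.11), LIF/STAT3 (0.29 to -0.23), DNA methylation (0.28 to -0.19), mitochondrially encoded (0.35 to -0.27), ATF4, ERK, Wnt and FoxO genes negative.

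Formative and core pluripotency genes were higher in PD-MK than in 2i. Of 14 formative genes 6 were higher and 0 lower (7 and 0 adjusted over the list alone, adjusted p = 7.87e-07, and adjusted p = 0.0541 with an estimated correlation; 7.84e-07 with the index term). Lefty1 had a log2 fold change of 1.57 ± 0.273 and Dnmt3a at 0.90 ± 0.191 (adjusted p = 0.00782). Of 18 core genes 7 were higher and 1 lower (8 and 2 adjusted over the list alone, adjusted p = 0.00229, and adjusted p = 0.0541 with an estimated correlation; 6.22e-04 with the index term). Lin28a had a log2 fold change of 2.01 ± 0.233 (adjusted p = 1.52e-04), Utf1 at 1.02 ± 0.193 and Cdh1 at -0.71 ± 0.146. The naive list was not called (1 higher and 0 lower of 20; 0 adjusted over the list alone, adjusted p = 0.437), though it was with the index term (adjusted p = 0.0458, and adjusted p = 0.193 with an estimated correlation). Nanog (0.19, adjusted p = 0.528) and Esrrb (0.37, adjusted p = 0.0785, but 0.0358 without 2i 3) were not called. ERK targets did not differ by the test (0 of 16, also adjusted over the list alone, adjusted p = 0.54), Dusp6 among them (0.52 ± 0.758, adjusted p = 0.726). FoxO targets were not called as a list (4 higher and 1 lower of 21, the same adjusted over the list alone, adjusted p = 0.333), while Irs2 (1.45 ± 0.274, adjusted p = 0.00398; 0.0197 with the index term) and Cited2 (1.64 ± 0.339) were higher. With fry the FoxO list was called higher (adjusted p = 8.32e-04). The Wnt/beta-catenin list was not called (1 higher of 5, the same adjusted over the list alone, adjusted p = 0.4).

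Cholesterol synthesis, glycolysis, p53 target and germline genes also differed between the inhibitor media, while ATF4 targets were not called (4 higher and 2 lower of 24 in PD-MK, 8 and 2 adjusted over the list alone, adjusted p = 0.154). Of 22 cholesterol synthesis genes 8 were higher in PD-MK and 0 lower (11 and 0 adjusted over the list alone, adjusted p = 3.85e-06, and adjusted p = 0.0561 with an estimated correlation; 2.65e-07 with the index term). The median of this list was 0.59 with TMM and 0.02 with spike-in scaling. Of 19 glycolysis genes 5 were lower and 0 higher (6 and 0 adjusted over the list alone, adjusted p = 0.00317, and adjusted p = 0.292 with an estimated correlation; 8 lower with the index term, adjusted p = 2.05e-07). Hk1 had a log2 fold change of -0.90 ± 0.169 and Gpi1, which shares 24.6% of its searched 3' sequence, at -0.67 ± 0.135. Of 18 p53 targets 5 were lower and 0 higher (8 and 0 adjusted over the list alone, adjusted p = 0.0014, and adjusted p = 0.0541 with an estimated correlation; 6.11e-06 with the index term). Ccng1 had a log2 fold change of -1.05 ± 0.178. Germline genes were lower (4 lower and 0 higher of 13, the same adjusted over the list alone, adjusted p = 0.00317, and adjusted p = 0.0561 with an estimated correlation; 6.22e-04 with the index term). Rhox5 had a log2 fold change of -2.04 ± 0.27 and Dazl at -1.36 ± 0.245. Ribosomal protein genes were lower by the pooled test (7 lower and 1 higher of 74; 10 and 1 adjusted over the list alone, adjusted p = 0.0323, and adjusted p = 0.339 with an estimated correlation), but not with the index term (adjusted p = 0.142) or without 2i 2 (0.0762).

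Neuroectoderm genes were higher in PD-MK than in 2i (2 higher and 0 lower of 5; 4 and 0 adjusted over the list alone, adjusted p = 0.00415, and adjusted p = 0.0878 with an estimated correlation; 0.00616 with the index term). Tubb3 had a log2 fold change of 1.92 ± 0.42. Primitive endoderm genes were higher (3 higher and 1 lower of 7; 4 and 2 adjusted over the list alone, adjusted p = 0.0378, and adjusted p = 0.147 with an estimated correlation; 0.0211 with the index term; 0.0638 without 2i 3). Col4a2 had a log2 fold change of 1.58 ± 0.213 and Sparc at 0.77 ± 0.138. Trophoblast genes were lower (4 lower and 1 higher of 7, the same adjusted over the list alone, adjusted p = 0.0441, and adjusted p = 0.148 with an estimated correlation). Eomes had a log2 fold change of -1.96 ± 0.361 and Krt18 at -1.88 ± 0.371. That call was lost with the index term (adjusted p = 0.0778), with library totals (0.0551), and without 2i 3 (0.0631), PD-MK 1 (0.0554) or PD-MK 2 (0.0918). Of the fibroblast markers only Vim and Col5a1 were tested. Col5a1 was higher in PD-MK than in Std (2.51 ± 0.357, adjusted p = 1.27e-04) and than in 2i (1.83 ± 0.329, adjusted p = 0.00303). Vim was called higher than in 2i (0.84, adjusted p = 0.0256), but not with the index term (0.102) nor without 2i 1 (0.0932), 2i 2 (0.114), PD-MK 1 (0.0533), PD-MK 2 (0.0567) or PD-MK 3 (0.0853). Adjusted over the list alone, both genes rose in PD-MK against Std and 0 changed in 2i.

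Genes that set 1 medium apart from both others were counted from the same fits. PD-MK set apart 645 genes (294 higher, 351 lower), among them Ddit4 (-3.11 ± 0.322 against Std, -2.11 ± 0.331 against 2i), Rhox5, Krt18, Cited2 and Sparc. With the index term the count was 460 and within indices 1 to 5 it was 132. It was 288 without 2i 1, 298 without 2i 2, 1036 without 2i 3, 290 without PD-MK 1, 429 without PD-MK 2 and 336 without PD-MK 3. The 2i medium set apart 389 genes (232 higher, 157 lower), among them Cdkn1a and Dazl, which were higher, and Lin28a, Lefty1, Dnmt3a and Ccnd2 (PD-MK against 2i 3.28 ± 0.581), which were lower. With the index term that count was 386 and within indices 1 to 5 it was 87. It was 212 without 2i 1, 202 without 2i 2, 245 without PD-MK 1, 232 without PD-MK 2 and 257 without PD-MK 3. Of the genes that rose in both media, 75 were higher still in PD-MK and 56 in 2i. Of those that fell in both, 54 were lower still in PD-MK and 39 in 2i.

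**Figure D3:**
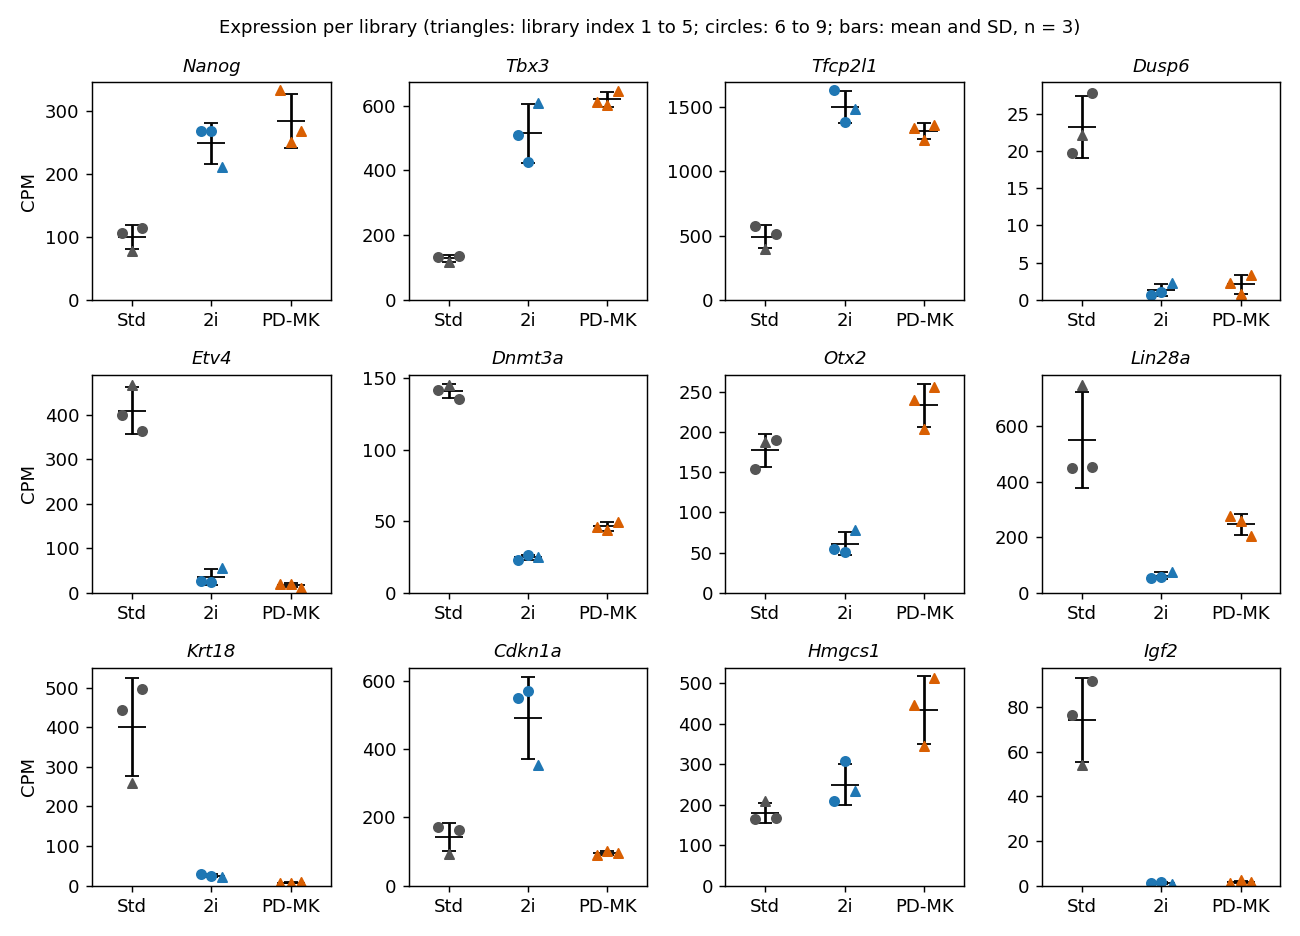
CPM (TMM-scaled) of 12 genes in each library by medium, with triangles for indices 1 to 5, circles for 6 to 9, and the mean and SD of 3 libraries. Nanog averaged 99.25 CPM in Std, 248 in 2i and 283.3 in PD-MK, while Cdkn1a averaged 142.4, 490.5 and 96.2 CPM.

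The remaining lists were not called in at least 1 of the comparisons or had too few members. LIF/STAT3 targets were not called in any (6 rose and 1 fell of 13 in PD-MK, 5 and 3 in 2i, 1 higher in PD-MK than in 2i, each the same adjusted over the list alone, adjusted p = 0.0836, 0.67 and 0.131). The list was called in PD-MK against Std with the index term (adjusted p = 0.0141), but not with an estimated correlation (adjusted p = 0.104). Spp1 rose in PD-MK (1.12 ± 0.195). DNA methylation genes were not called (5 rose and 5 fell of 15 in PD-MK, 2 and 4 in 2i; 6 and 5, and 4 and 4, adjusted over the list alone, adjusted p = 0.814 and 0.127), with a median of 0.33, a mean of 0.01 and a downward test direction in PD-MK. Prdm14 rose in PD-MK (1.68 ± 0.272) and in 2i (1.98 ± 0.264), and Dnmt3l fell in both (-0.87 ± 0.17 and -1.26 ± 0.17). The 2-cell list had 1 tested gene, Pramel6, which rose in PD-MK (4.48 ± 0.507, adjusted p = 1.73e-05) and in 2i (4.77 ± 0.471, adjusted p = 3.9e-06). Mesendoderm genes had 3 tested members and were not called (1 rose and 1 fell in PD-MK, 2 and 1 in 2i; 1 and 2, and 2 and 1, adjusted over the list alone, adjusted p = 0.954 and 0.737), with a median of -0.95, a mean of -0.14 and an upward test direction in PD-MK.

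Mitochondrially encoded genes were not called in PD-MK against Std (3 rose and 0 fell of 13; 5 and 0 adjusted over the list alone, adjusted p = 0.0951, but 0.00896 without PD-MK 2) or against 2i (3 higher; adjusted p = 0.0793, but 0.00394 without PD-MK 2), and neither call without PD-MK 2 stayed with an estimated correlation (adjusted p = 0.16 and 0.124). The collision correction took the median against Std from 0.42 to 0.30 (95% interval 0.0176 to 0.455) and that against 2i from 0.35 to 0.06 (-0.174 to 0.265), although the median drop per gene was only 0.00922 (-0.00805 to 0.106) and 0.021 (-0.00548 to 0.131). Of these mt-Co1 rose against Std (1.22 ± 0.185), with 95.3% of its searched sequence shared with other entries. Oxidative phosphorylation genes were not called (1 of 38 rose in PD-MK and 1 in 2i; 0 and 1 adjusted over the list alone, adjusted p = 0.981 for each). Ribosomal protein genes were not called against Std (2 rose and 12 fell of 74 in PD-MK; 0 and 11 adjusted over the list alone, adjusted p = 0.265). Only 1 rose and 1 fell with the index term (adjusted p = 0.51). Not called either were ATF4 targets (2 rose and 3 fell of 24; 0 and 2 adjusted over the list alone, adjusted p = 0.67), with Ddit4 and Chac1 (-1.77 ± 0.257) lower. In PD-MK against Std p53 targets were not called (2 rose and 5 fell of 18, the same adjusted over the list alone, adjusted p = 0.659), with Tigar higher (1.10 ± 0.158) and Perp lower (-3.06 ± 0.5). The cell cycle list was not called (4 rose and 5 fell of 32; 5 and 6 adjusted over the list alone, adjusted p = 0.826), with Mki67 lower (-1.05 ± 0.198). Its median was 0.08, its mean -0.01 and its test direction downward. Primitive endoderm genes were not called (2 rose and 2 fell of 7, the same adjusted over the list alone, adjusted p = 0.443), with Sparc (1.68 ± 0.142) and Lamc1 (2.15 ± 0.271) higher and Lamb1 (-1.44 ± 0.226) and Lama1 (-0.92 ± 0.167) lower.

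**Figure D4:**
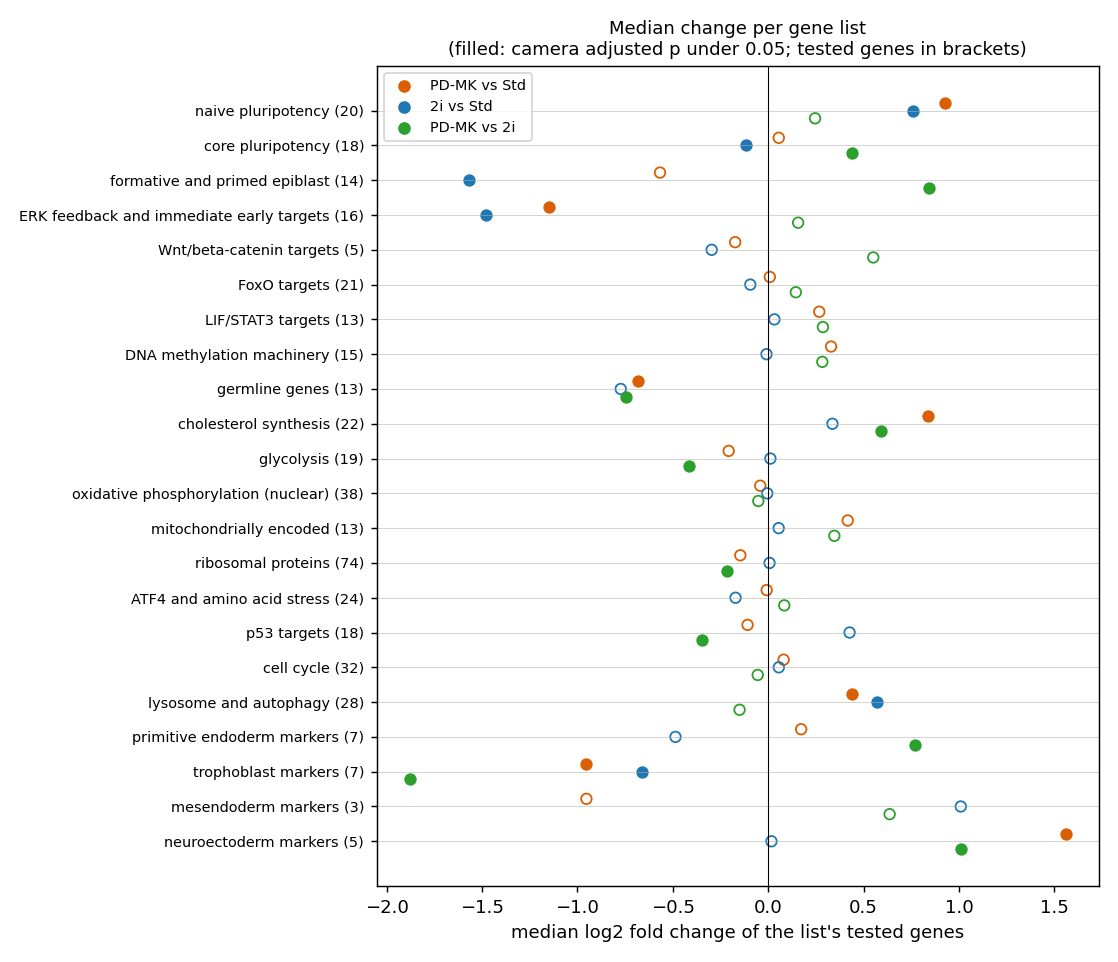
Median log2 fold change (horizontal axis) of each of 22 gene lists in the 3 comparisons, with filled symbols where the camera test gave an adjusted p under 0.05. Naive pluripotency lies at 0.93 in PD-MK and 0.76 in 2i against Std, and cholesterol synthesis at 0.84 and 0.34. In PD-MK against Std both stay positive with spike-in scaling (0.35 and 0.32) where the core list turns from 0.06 to -0.52. With that scaling cholesterol synthesis lies at 0.35 in 2i against Std, and at 0.02 instead of 0.59 in PD-MK against 2i.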

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

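Splits of the libraries and the tests of depth, GC content and carry-over were set before their values were seen, and the tests of the index batch and of UMI saturation were chosen after results were seen.

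ERCC spike-in transcripts averaged 212 ± 54.1 UMIs per M gene UMIs, without TMM scaling, in PD-MK, against 154.5 ± 31.4 in Std and 159.2 ± 53.4 in 2i (SD, n = 3; exact permutation test of PD-MK against Std, two-sided, p = 0.2, smallest possible 0.1). These are data on which no result was reported. A higher spike-in share could reflect less RNA put in, which the input range of 30 to 60 ng allows, and with inputs set by mass it does not measure RNA per cell. With spike-in scaling, set from 180 to 303 ERCC UMIs per library, 900 genes changed in 2i against Std, and 2171 in PD-MK against Std, of which 304 rose. Because the spike-in share followed the index, this scaling carries the index pattern into the comparisons with PD-MK.

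Std 2 and 2i 3 deviated from their group means together, with a correlation across genes of 0.421, which was 0.43 after thinning all libraries to the shallowest and 0.421 after removal of GC trends, arguing against depth and GC content. A batch holding indices 1 to 5 predicts that the shift of these libraries resembles the difference of PD-MK from the libraries of indices 6 to 9, and the correlation was 0.294 seen from 2i and 0.356 seen from Std, between libraries that do not overlap. Carry-over of PD-MK RNA predicts a like shift of genes that separate PD-MK, but over such genes the median position was 1.53% of the way in Std 2 (95% interval -0.27 to 4.54) and 7.74% in 2i 3 (0.425 to 12.9). By another measure, the summed shift over the summed gap to PD-MK, the position was 75.7% in Std 2 and 89.8% in 2i 3. That measure was taken over genes chosen because they shifted in the other of these libraries. The bound set beforehand, under 10% with the interval, was met for Std 2 but not for 2i 3, over 40 genes, so some carry-over into 2i 3 stays open. The correlations of 0.294 and 0.356 suggest a batch by index, but what the index stands for is not known here, and a biological difference between culture rounds would look the same.

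The most abundant genes lay higher in PD-MK. The 218 genes with a mean count over 1000 had a median log2 fold change of 0.31 against Std (95% interval 0.25 to 0.369) and 0.35 against 2i, and -0.05 in 2i against Std. UMI saturation could produce this, since the PD-MK libraries were on average the shallowest and lost fewer UMIs. After collision correction the medians were 0.152 (0.0769 to 0.228) and 0.176 (0.108 to 0.231), and the median drop per gene was 0.11 (0.0898 to 0.128) and 0.128 (0.104 to 0.137). Saturation may thus be part of the cause, if the UMI had 6 bases. Whether it was the whole is not settled. The intervals come from resampling genes and hold no spread between libraries. The correction also takes all tags as equally likely, and an effect of the index on these genes was not tested.

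For the numbers of changed genes, each comparison has 10 splits of its 6 libraries into 3 and 3, too few for a share under 0.05. The real grouping gave 2651, 1965 and 1215 genes, and the highest count of any other split was 0 by edgeR in each comparison (1 split in each, the real one, reached its own count). At an unadjusted p under 0.05 the other splits gave up to 632, 855 and 911 genes. Every other split put both media in each group, so the difference between the media widened the spread within groups. Their counts therefore do not measure what a random grouping of like libraries would give.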

How the results depend on the processing

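Among the tests listed here, those of the index, of Std 2 and 2i 3, of thinning, of GC trends and of collisions were chosen after results were seen. Of the values for named genes under all alternatives 6726 kept direction and call, 698 lost the call, 24 gained it and 8 changed sign, and none of the latter was called in both directions. For list tests 1481 kept, 45 lost and 57 gained the call, 22 of the losses with an estimated correlation and 23 of the gains with fry. Gains with fry included FoxO targets, higher in PD-MK against Std (adjusted p = 0.0206) and 2i (8.32e-04) but lower in 2i against Std (0.00821). They also included LIF/STAT3 targets, higher in PD-MK against Std (5.41e-04), and cholesterol synthesis, higher in 2i against Std (0.0173). By fry against Std, p53 targets were lower in PD-MK (0.00824) and higher in 2i (1.27e-04). Of the counts and correlations 213 stayed and 75 moved. Some of these settings held fewer libraries or UMIs, but why the values moved was not tested. Leaving out 1 library gave 1739 to 3084 genes in PD-MK against Std, 1514 to 2096 in 2i against Std, 551 to 1975 in PD-MK against 2i, 288 to 1036 set apart by PD-MK, 202 to 564 by 2i, and correlations of 0.699 to 0.763. DESeq2 gave 2253, 1694 and 1058 genes and a correlation of 0.61, and no filter gave 0.594. With the replicate block 2288, 1707 and 827 genes changed. Same-number libraries correlated from -0.37 to 0.163, 1 of 9 pairs over 0.1, and 2 of 9 libraries were closest to their own number, so the numbers do not show a pairing. Thinning to the shallowest library gave 1249 genes in 2i against Std, 784 in PD-MK against 2i, 419 set apart by PD-MK and 233 by 2i, a limit set by depth.

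Without Std 2 and 2i 3, where PD-MK and index coincide, 2733 genes differed between PD-MK and 2i, 1669 were set apart by PD-MK and 686 by 2i, and the correlation was 0.713. With a term for those libraries the values were 2902, 1799, 839 and 0.719. PD-MK and index coincide there too, since PD-MK is set against the remaining Std and 2i libraries. The fit is that of the index term written differently, and both gave 2823 genes in 2i against Std. With the index term, which places PD-MK on the low side, the values were 904, 460, 386 and 0.764. The pair term is thus not a separate check on the index. Indices 1 to 5 alone gave 1227 genes in PD-MK against Std, 682 in 2i against Std, 279 in PD-MK against 2i, 132 set apart by PD-MK and 87 by 2i, with fewer libraries, and a correlation of 0.779. Spike-in scaling gave 900 genes in 2i against Std and 204 set apart by 2i. With it these log2 fold changes changed sign: in PD-MK against Std Rif1 (-0.0334), Cox5a (-0.0117), Rpl5 (-0.118), Esrrb (-0.0316) and Sox2 (-0.0537), and in PD-MK against 2i Pecam1 (-0.0195), Grn (-0.108) and Sox2 (-0.0107). By construction this scaling lowered all genes in PD-MK (all-gene medians -0.56 and -0.57), about as much as these genes had risen with TMM.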

Other observations

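The list of imprinted genes and the tests on it were chosen after results were seen, except that on Std 2 and 2i 3, set before its values were seen.

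Imprinted genes, which are expressed from 1 parental allele under DNA methylation marks, included 13 that changed in both inhibitor media of 35 tested. H19 fell from 94.1 CPM in Std to 8.26 in PD-MK and 10.7 in 2i (log2 fold changes -3.55 ± 0.27 and -3.11 ± 0.233, SE, n = 3 per group). Its neighbour Igf2 fell by 5.31 and 5.82, with its searched sequence shared with Gm49394, and Phlda2 (-3.33 and -3.50), Sfmbt2 (-3.10 and -3.25), Peg10 (-4.49 and -3.69) and Cdkn1c (-2.79 and -4.71) fell as well. Meg3 (3.09 and 2.58), Plagl1 (2.96 and 4.63) and Ddc (2.11 and 1.40) rose. Peg3 fell in 2i (-2.13, adjusted p = 1.61e-06) but was not called in PD-MK (-0.27, adjusted p = 0.289), and was higher in PD-MK than in 2i (1.86, adjusted p = 6.19e-05). Grb10 was lower in PD-MK than in 2i (-1.64, adjusted p = 0.00531).

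Of 55 imprinted genes 35 were tested, and 13 changed in both media (9 fell, 4 rose), against a mean of 4.73 and a highest value of 13 in 10000 lists matched for abundance (permutation test, p = 5e-04). All 13 were still called without Std 2 and 2i 3, but those libraries lie towards PD-MK and PD-MK coincides with index without them, so this does not exclude an effect of the index. The p does not show that imprinted genes as a class respond more often than genes of like abundance. The list was written after Igf2, Plagl1 and Nnat were seen among the largest changes, and imprinted genes lie in clusters while the matched lists treat genes as independent.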
